A study of Forsythia koreana with 2 samples.

How the data were processed

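RNA was extracted from flower and leaf tissue of Forsythia viridissima var. koreana, a yellow-flowered shrub of the olive family, from plants that the labels give as 2 years old. The plants grew outdoors at a medicinal plant research garden in Japan. Poly(A) RNA was selected on oligo(dT) beads, fragmented and turned into strand-specific Illumina libraries, per the labels' protocols. There was 1 library for flower and 1 for leaf, and the labels do not say how many plants went into each. Trimmomatic and RSEM are named in the submitters' processing notes, without versions. RSEM assigns reads to transcripts and estimates how many each transcript received. The assembler, the aligner and their settings are not given in the sources used here.

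The authors deposited 1 RSEM table per tissue, holding expected counts, TPM, FPKM and the percent of each gene's expression taken by each transcript, per the file headers. The expected counts are the estimated number of fragments per transcript, not normalized, per the file headers. The TPM and FPKM values were made by the authors with RSEM from those counts, the effective transcript length and the library total, per the file headers, with no further scaling between tissues. A joined table of the series, also deposited by the authors, repeats the FPKM of both tissues, and 0 of its 69458 transcripts differed from the tissue tables. Every expected count was a whole number (0 of 69458 values in flower and 0 in leaf were not, at a tolerance of 0). RSEM normally gives fractions to transcripts that share reads, so reads shared between similar transcripts were not split in these values. What happened to such reads is not given in the sources used here, and a transcript with a near-identical partner is uncertain in both level and ratio. The deposited percent within each gene was either 0 or 100, because each of the 69458 transcripts has its own gene identifier in the tissue tables. That column was therefore not used for isoforms.

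The files do not pair the identifiers with gene names or sequences, and no reference genome or annotation was used here. The lists of lignan, phenylpropanoid, flavonoid, carotenoid, terpenoid, photosynthesis, floral identity, pollen, vascular and contaminant markers drawn up for the study could not be applied, and no gene, pathway or cell type is named. The identifiers have a stem of the form component, locus and isoform, as in the naming scheme of the Trinity assembler. Transcripts with the same stem up to the isoform number were treated as 1 locus, which gave 56696 loci in 50810 components.

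The flower library summed to 5466947 expected counts and the leaf library to 4982637. The floor for a transcript with no count was set at 3 counts, or a CPM of 0.549 in flower and 0.602 in leaf. The 95% Poisson interval used for the named transcripts reaches 3.69 counts in that case, so the floor is not an upper limit. Intervals and floors cover counting error only. The reads carry no molecular identifiers, so copies of the same molecule could be counted separately and the intervals may be too narrow. With 1 library per tissue there is no replicate error, so no test between tissues was made and no p-value is given. Every difference below is between these 2 libraries.

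A transcript was called higher in a tissue when its FPKM was 1 or more in at least one tissue and its log2(FPKM + 1) differed by 2 or more. Because of the pseudocount of 1, this scale understates the change of scarce transcripts. As a second description, the exact 95% Clopper-Pearson interval of each transcript's flower to leaf count ratio, scaled by library totals, was compared with 2-fold. These intervals are per transcript and not adjusted for the number of transcripts. A dominant isoform was the transcript with the highest TPM of a locus, at 60 percent or more of the locus in each tissue, for loci with 50 or more counts in each. The transcripts named are the 2 with the largest difference in each direction among those with 100 or more counts in the higher tissue.

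Both rules were tested on simulated data drawn for all 69458 transcripts from the mean levels and totals of the flower against leaf comparison. The draws held Poisson counting error only, with no variation between plants or library preparations. With 200 transcripts changed, all drawn from those with 100 or more counts over both libraries, the counting interval recovered 81 of 100 at 3-fold and 100 of 100 at 8-fold, and the 4-fold size rule recovered 0 of 100 and 100 of 100. Among 69258 unchanged simulated transcripts the counting interval called 15 and the size rule 3278, but neither called any of the 15951 with 100 or more counts. Alternatives were other pseudocounts, minimums, units and scalings, sums per locus and other isoform limits. TMM factors came from edgeR 4.0.16 in R 4.3.3 on the counts, and all other steps used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. The rules and these alternatives were fixed before the data were examined, except that the isoform rule was planned on the deposited percent within each gene and was moved to TPM within identifier stems, as were the sums per locus, once that column had been seen. Thinning of the flower library and a minimum of 100 counts over both libraries were added after seeing the data.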

Results

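Transcript levels were measured by RNA sequencing in 1 flower library and 1 leaf library of Forsythia viridissima var. koreana. The deposited set held 69458 transcripts with a summed length of 53.6 megabases, a median length of 470 bases (quartiles 296 and 1002) and an N50 of 1198 bases. The flower library held 5466947 expected counts and the leaf library 4982637. The median transcript had 8 counts in flower and 6 in leaf.

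More transcripts were detected in flower, the deeper library, than in leaf, and the libraries were not thinned to equal depth for these numbers. In flower 64269 transcripts (92.5%) reached an FPKM of 1, against 55663 (80.1%) in leaf. Of the 69044 that did so in either tissue, 50888 (73.7%) were found in both, 13381 (19.4%) in flower alone and 4775 (6.92%) in leaf alone. Flower left 3510 transcripts without a count and leaf 11008, of which 274 had none in either tissue. Most of the transcripts found in a single tissue were scarce. A total of 2919 of the 13381 flower transcripts and 1093 of the 4775 leaf transcripts had 10 or more counts in their tissue. A single read is worth an FPKM of 1 or more for 35.7% of transcripts in flower and 37.9% in leaf, so for these short transcripts detection means 1 read. With 10 or more counts required in place of the FPKM minimum, 32879 transcripts were detected in flower and 29324 in leaf.

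Expression was more concentrated in leaf than in flower. The 10 most abundant transcripts took 6.03% of the TPM in leaf and 3.75% in flower, and the 100 most abundant took 19.4% and 12.9%. The top 1000 took 44.6% in leaf and 33.9% in flower. A total of 1486 transcripts made up 50% of the TPM in leaf, against 3212 in flower. The most abundant leaf transcript by TPM, 925 bases long, held 99605 counts or 2.00% of the leaf library, and 20869 counts or 0.382% of the flower library. Its share of the counts was 5.24-fold higher in leaf (95% interval 5.16 to 5.32, counting error only). The most abundant flower transcript by TPM, 614 bases long, held 17333 flower counts, fewer than the highest count of 48572 in that library. It reached an FPKM of 7080 in flower and 1580 in leaf, and its share of the counts was 4.44-fold higher in flower (95% interval 4.28 to 4.60).

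**Figure D1:**
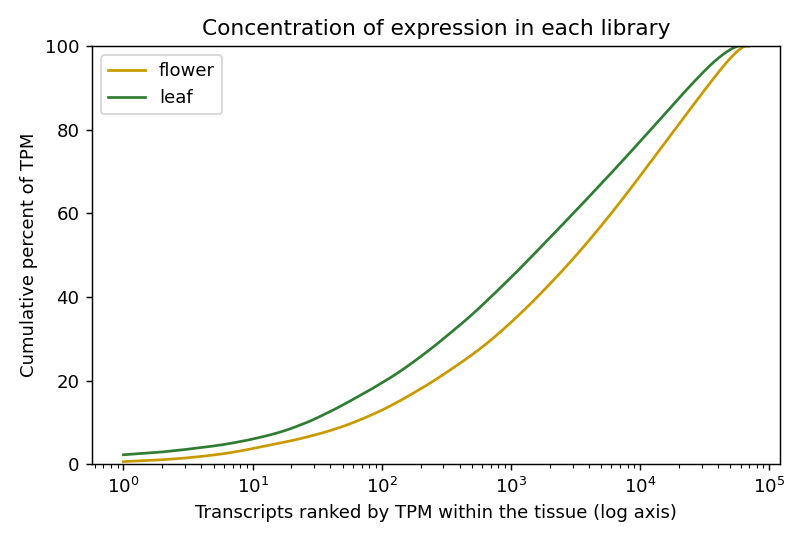
Cumulative percent of TPM (vertical axis) taken by transcripts ranked by TPM within each tissue (horizontal log axis), for the 1 flower and 1 leaf library. The leaf line lies above the flower line, passing 19.4% at the top 100 transcripts against 12.9% in flower.

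The overlap of the most abundant transcripts of the tissues grew with the length of the list. Flower and leaf shared 1 of their top 10 transcripts by TPM, 24 of their top 100 and 478 of their top 1000. Of the flower top 100, 49 were higher in flower by 2 or more in log2(FPKM + 1) and 2 were higher in leaf by that margin. Of the leaf top 100, 63 were higher in leaf and 1 was higher in flower. In the top 1000 most transcripts met neither limit, with 274 of the flower list higher in flower and 52 in leaf, and 322 of the leaf list higher in leaf and 7 in flower. Across the 69044 detected transcripts, log2(FPKM + 1) in flower and leaf had a Pearson r of 0.49 and FPKM a Spearman rho of 0.39. Among the 16151 with 100 or more counts over both libraries these were 0.47 and 0.49. These correlations are across transcripts, which are not independent replicates.

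The direct comparison of flower with leaf asked which transcripts set the tissues apart. By the size rule 11934 transcripts (17.3% of those detected) were higher in flower, 5422 (7.85%) were higher in leaf and 51688 (74.9%) met neither limit. The flower-high set, chosen for its higher flower level, held 20.9% of the flower counts and 1.46% of the leaf counts. The leaf-high set held 22.6% of the leaf counts and 3.15% of the flower counts. The flower-high transcripts had a median length of 314 bases and a median of 5 counts over both libraries, and the leaf-high ones 386 bases and 11 counts. In simulated libraries, which varied by counting error only, the same rule called 3278 of the 69258 transcripts that had been left unchanged. None of these had 100 or more counts. Among transcripts with 100 or more counts 1289 were higher in flower and 1111 in leaf. After TMM scaling, which lowers every flower to leaf difference by 0.25 on the log2 scale before the pseudocount, 1126 of these were higher in flower and 1344 in leaf.

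**Figure D2:**
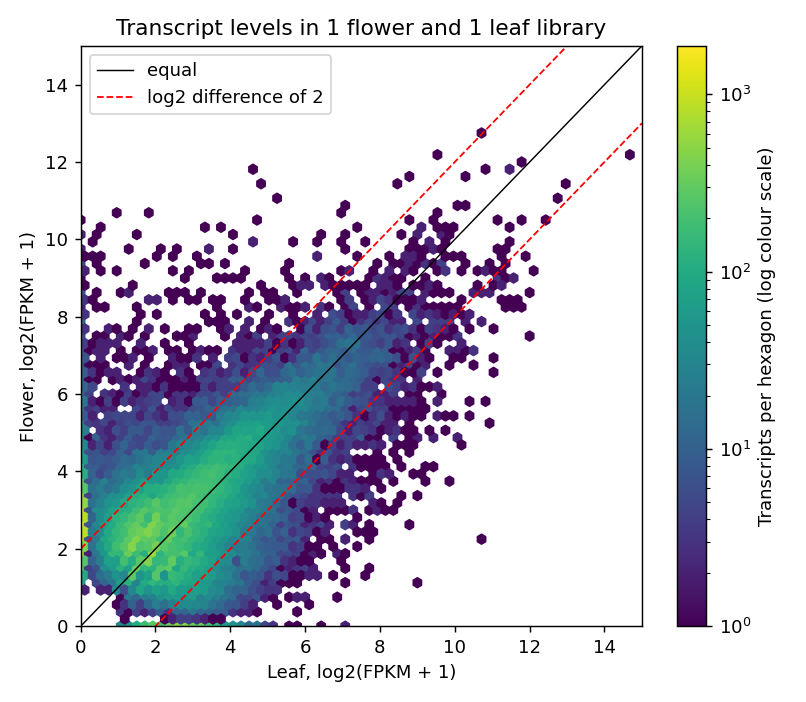
Flower level against leaf level of the 69044 detected transcripts, both as log2(FPKM + 1), with colour giving the number of transcripts per hexagon on a log scale. The solid line marks equal levels and the dashed lines a log2 difference of 2, beyond which lie 11934 transcripts on the flower side and 5422 on the leaf side.

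The preponderance of flower-high transcripts was found among scarce and short ones. Of the detected transcripts with 1 to 5 counts over both libraries, 31.1% were higher in flower and 9.49% in leaf. Above 100 and up to 300 counts these shares were 6.98% and 5.86%. Above 1000 and up to 10000 counts, 236 of 1742 transcripts were higher in flower and 209 in leaf. Of the 60 transcripts above 10000 counts, 9 were higher in flower and 16 in leaf. By length, 30.5% of detected transcripts under 300 bases were higher in flower and 10.8% in leaf, against 7.24% and 6.26% from 1000 to just under 2000 bases. Transcripts of 2000 bases or more again leaned to flower, with 326 higher there and 164 in leaf.

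**Figure D3:**
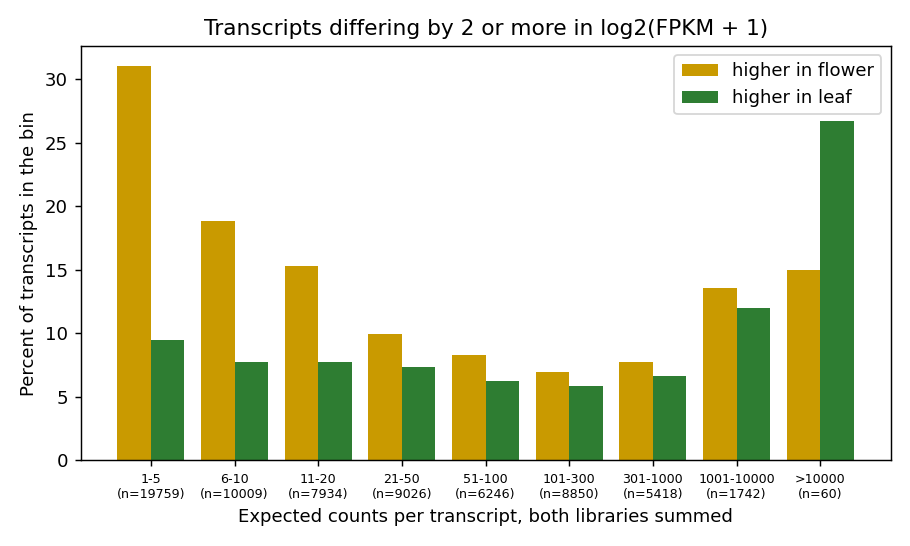
Percent of detected transcripts (vertical axis) that were higher in flower or in leaf by 2 or more in log2(FPKM + 1), by the transcript's expected counts summed over both libraries (horizontal axis, with n transcripts per bin). The bars differ most at 1 to 5 counts, at 31.1% for flower and 9.49% for leaf, and above 10000 counts the leaf bar is the taller.

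Judged by counting error, 4982 transcripts had a flower to leaf ratio whose whole 95% interval lay above 2-fold, and 3893 had one wholly below the reverse limit. The flower part of these was 56.1% when scaled by library totals. It was 44.0% with TMM scaling, with 3855 on the flower side and 4904 on the leaf side, so which tissue had more such transcripts depended on the scaling. Of the transcripts past the size rule, 3645 flower-high ones (30.5%) and 2605 leaf-high ones (48.0%) also passed this interval rule.

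Abundant transcripts without a single read in the other tissue were nearly all flower ones. Of 10598 transcripts with 100 or more counts in flower, 208 had no count in leaf and 362 had at most 3. Of 8844 with 100 or more counts in leaf, 3 had no count in flower and 20 had at most 3. The 208 flower transcripts had a median length of 1166 bases and a median of 258 flower counts.

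On the log2(FPKM + 1) scale, which ranks transcripts without a leaf read by their flower FPKM, the largest flower-high difference was that of transcript TR23539|c3_g1_i3|c0_g1_i1 (300 bases), with 1093 counts in flower (95% Poisson interval 1029 to 1160) and 0 in leaf. Its FPKM was 1486 in flower, 342-fold the leaf level that 3 counts would give. The 95% interval of its flower to leaf count ratio had a lower limit of 270. Transcript TR23322|c0_g1_i1|c0_g1_i1 (1338 bases) held 7292 counts in flower (7126 to 7461) and 0 in leaf. Its FPKM of 1138 was 2223-fold the leaf level at the same floor, and the lower limit of its count ratio was 1801. On the leaf side, TR29274|c0_g2_i1|c0_g1_i1 (269 bases) had 947 counts in leaf and 2 in flower, a ratio of 520 with a 95% interval from 143 to 4296. Transcript TR21796|c2_g1_i2|c0_g1_i1 (727 bases) had 1479 counts in leaf and 4 in flower, a ratio of 406 with an interval from 158 to 1491. The files give these transcripts no gene name or genome position. By the identifier stems, TR23539|c3_g1_i3|c0_g1_i1 lies in a component of 4 transcripts and each leaf-side transcript in a component of 2. TR23322|c0_g1_i1|c0_g1_i1 is the only transcript of its component. Reads shared between similar transcripts were not split, so a count or ratio is uncertain where a partner is near-identical.

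Isoform use was compared within loci that held several transcripts. Of 7522 such loci, 4519 had 50 or more counts in each tissue, and 1199 of these had a transcript at 60% or more of the locus in each tissue. The dominant transcript was the same in both tissues in all but 30 of the 1199 loci (2.50%). Without the 60% minimum the top transcript differed in 1190 of 4519 loci. Reads shared between isoforms were not split in the counts, so these shares rest on the reads that RSEM placed whole. The deposited identifiers skip some isoform numbers, and isoforms absent from the deposited set could not be compared.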

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

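Of 59 alternatives, 31 left the value within its limit (1.5 times for a count, a 95% interval for a share or correlation) and 28 moved it. Each count was judged by itself, so the 31 include the scalings that turned the order of the tissues at 2-fold. The interval for a correlation treats transcripts as independent, which they are not, so a very small change can count as a move. No paired analysis was possible because each tissue has 1 library. For the same reason no library could be left out. With a pseudocount of 5, 1490 transcripts were higher in flower and 1038 in leaf. A log2 difference of 1 gave 22771 and 11927. A minimum of 20 counts over both libraries gave 2779 and 2199, and one of 100 counts, added after seeing the data, gave 1289 and 1111. Thinning the flower library to the leaf total, also added later, gave 11791 and 5622, or 67.7% on the flower side. By the size rule flower had the larger number in each of the 13 settings tried one at a time, but not with TMM scaling and 100 counts together. The other settings, among them TPM, TMM and median-of-ratios scaling, gave 8637 to 15729 flower and 4615 to 7506 leaf transcripts. Removing the minimum FPKM could not change the calls, because any transcript past the log2 limit also passes that minimum. At a minimum FPKM of 5, 38234 transcripts were detected in flower and 31277 in leaf, and 10 or more counts left 32879 and 29324. A counting interval wholly beyond 4-fold was met by 2080 flower and 1384 leaf transcripts. At 2-fold the order turned to leaf with TMM scaling (3855 flower, 4904 leaf) and with median-of-ratios scaling (3872 and 4877). Pearson r was 0.49 without a minimum, 0.41 at a minimum FPKM of 5, 0.27 with a pseudocount of 0.1 and 0.52 for levels summed per locus, and Spearman rho was 0.39, 0.37 and 0.41 in the settings other than the pseudocount. The dominant isoform differed in 1190 of 4519 loci without a minimum percent and in 7 of 449 with 200 or more counts, against 30 of 1199. As a share of counts in place of TPM, the top 10 transcripts took 7.41% of leaf, the top 100 took 13.9% of flower and 20.04% of leaf, and the top 1000 took 38.1% of flower and 45.0% of leaf. The cause was not tested for any of these moves, other than that stricter minimums leave fewer transcripts to count. Depth limits every statement on transcripts with few counts.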

Other observations

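The tests of the excess of flower-high transcripts, of the flower library's greater depth and of misassigned reads were chosen after the result was seen, and that of assembly components before. Different loci of one assembly component, as read from the identifier stems, tended to be higher in the same tissue. Among 2099 loci with 100 or more counts that passed the size rule, 69 components held 2 or more, of which 27 had all of them higher in flower, 37 all higher in leaf and 5 some of each. The hypothesis that this is chance pairing was tested by shuffling directions between loci. Of 89 pairs 84, or 94.4%, went the same way, against at most 61.8% in 100 shuffles. Related genes with shared tissue preference may produce this, and so may fragments of a single gene assembled as separate loci, and without the sequences the 2 were not separated.

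Flower had more transcripts past the size rule than leaf, 11934 against 5422. With TMM scaling flower still held 63.5% of the calls, down from 68.8%. That does not decide whether abundant leaf transcripts lowering the level of the rest are the cause. Of the 13381 transcripts found in flower alone, 10693 had no leaf count, and scaling cannot change a level without a read. Counting noise by itself, with levels scaled by library totals, is argued against. Transcripts with 1 to 5 counts took 64.8% of their reads from flower (95% Clopper-Pearson interval 64.4 to 65.1), against 52.3% of all reads. Among simulated transcripts left unchanged, flower held 54.9% of the calls. Both comparisons take the library totals as the scale, and the interval covers counting error only. They do not address noise combined with a shift in scaling or with uneven assembly of scarce transcripts. Most of the excess lay in transcripts called on a few reads, since a minimum of 100 counts alone took the flower share of calls to 53.7%, and the minimum and TMM scaling together to 45.6%. What these scarce transcripts are stays open: rare flower transcripts, unprocessed RNA, DNA carry-over or an assembly built from more flower sequence may each contribute, and none of these was tested.

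A total of 208 transcripts with 100 or more flower counts had no leaf read, against 3 the other way. The greater depth of the flower library does not account for this, since thinning it to the leaf total left 197 against 3, a ratio of 65.7. Leaf reads misassigned to flower at one common rate could keep leaf transcripts from reading 0 there, and this stays open. Exact Poisson upper limits, adjusted by Bonferroni, were taken for the flower to leaf ratio of 1053 leaf-high transcripts with 100 or more leaf counts. The lowest of these limits allows up to 1.32 flower reads per 100 leaf reads. At that rate 50 of the 8844 leaf transcripts with 100 or more counts could owe all their flower reads to misassignment, at a limit of 0.05 each. At a Bonferroni limit, the more lenient choice, the number was 172, too near 208 to decide. The other way, the highest common rate was lower, at 0.148 leaf reads per 100 flower reads. Whether misassignment was equal in both directions was not tested. Also open is a biological explanation, that green parts collected with the flowers express leaf transcripts at a low level, which was not tested because no transcript is named.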
